A study of Mus musculus with 36 samples.

How the data were processed

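Gene expression was measured on 36 Affymetrix mouse genome arrays, in 12 groups of 3 arrays. The groups were read from the sample titles, where a letter A after the replicate number marks atrial chambers, and from the source field. The 6 arrays of E16.5 carry that day in the title and day 15.5 in the description. The title's day was used.

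The deposited values were intensities on a linear scale, with 1 value for each of 45101 probe sets on each array. How the authors computed and scaled them is not given in the sources used here. The 2% trimmed mean lay between 499.9 and 500.3 on the 36 arrays, so that each array had already been brought to one level. Array medians lay between 143.8 and 210.7, and the highest value of an array between 12532 and 26432. This scaling was kept. The residual SD of an array was between 0.17 and 0.31 on the log2 scale. The log2 ratio of 3' to 5' control probe sets lay between 0.21 and 0.47 for actin and between -0.38 and -0.23 for Gapdh. The highest correlation between a pair of arrays was 0.984, and no pair of arrays held the same values. With 3 arrays a group, the number of arrays limits the precision.

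After 64 control probe sets were left out, 45037 remained, and 34945 of these were annotated to 1 gene symbol. A pseudocount of 17, set as 10% of the median of all values, was added before taking log2. Probe sets above the median of all values, 171.8, on at least 3 arrays were tested, which gave 27256 probe sets and 12959 genes. A gene was represented by its probe set with the highest mean, chosen without regard to the groups. Hcn4, which was to be named in each comparison, had no measured probe set.

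R 4.3.3 with limma 3.58.1 fitted the 12 group means to the 36 arrays with 24 residual degrees of freedom. Moderated statistics used an intensity trend, with 5.7 prior degrees of freedom, and were two-sided. P-values were adjusted by the Benjamini-Hochberg method over the 27256 probe sets, within each of 15 comparisons. An adjusted p below 0.05 was called a change. The comparisons were atrium against ventricle at each of 5 ages and as their mean, 3 pairs of ages within each chamber, and the difference between the chambers in the change from E12.5 to E18.5. The last 2 were E11.5 against E10.5, and the mean of both chambers at E12.5 against E11.5. All values are log2 differences with the standard error (SE) of the fit, which pools the spread of the 12 groups.

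The comparisons, the thresholds, the gene lists and the rule for naming genes were fixed before the data were examined. Named genes were the 10 largest positive and the 10 largest negative called changes whose groups did not overlap. For the mean over ages the 5 differences had to share a sign, and the difference between chambers had no overlap rule. Up to 4 called members of each list with the largest change were added, and a fixed set of heart genes was given in each case where measured, including Nppa, Myl7, Myl4, Sln, Myl2, Myh6, Myh7, Irx4, Hey2, Nkx2-5, Tbx5, Tnni1, Tnni3, Hcn4, Bmp10 and Nr2f2; 1 gene of that set is not reported here. Not every gene that the rule allows is printed. Genes given for a single age or a shorter interval were chosen after their values were seen.

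There were 27 lists with 405 members, of which 382 had a probe set of their own gene alone and 351 were measured. They covered atrial chamber genes, ventricular chamber genes, sarcomere, calcium handling and ion channels, cardiac transcription factors, endocardial cushion and valve, conduction system and pacemaker, cell cycle, fatty acid oxidation, glycolysis, oxidative phosphorylation with the TCA cycle, immediate early and heat shock genes, and hypoxia response. Cell and tissue lists covered fibroblast and extracellular matrix, epicardium, endothelium and endocardium, smooth muscle, adult erythroid cells, embryonic globins, macrophages and leukocytes, liver, neural tissue, somite and skeletal muscle, foregut and lung, thymus, brown fat, and sex-linked genes. Some genes belong to more than 1 list. The 25 lists with at least 3 measured genes were tested against the other genes with camera in limma, with a preset correlation of 0.01 between genes and adjustment over the lists of a comparison. The same test with an estimated correlation, and fry, were alternatives.

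Alternatives fixed in advance were quantile normalization, median centring, pseudocounts of 1 and 68, no filter, a strict filter at the 75th percentile (583.3), only the arrays of the compared groups, no intensity trend, array weights, the replicate number as a block, the mean of a gene's probe sets, and leaving out each array in turn. Added after seeing the data were the mean without E14.5, the fit without 3 atrial arrays with high lung genes, the fit without the 2 arrays with the highest Alb (those with high liver genes), and leaving out each array in turn for the lists at single ages and over shorter intervals. The median log2 difference of the 27256 probe sets was at most 0.10 in size in each comparison, with the deposited scaling, quantile normalization and median centring. For each comparison, other splits of the same arrays were fitted in the same way.

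The procedure was tested on simulated data, with 27256 probe sets of which 200 were changed. In the mean over 5 ages, 88.1% of changes of log2 0.5 were recovered, with 12 false calls among 204. For the ventricle at E18.5 against E12.5, 38.8% were recovered at log2 0.5 and 80.6% at log2 1. For the difference between chambers, 43.3% were recovered at log2 1 and 86.4% at log2 2. Each simulated probe set had the same SD on all arrays, which is what the pooled fit assumes. The real arrays differed in spread, with array weights from 0.28 to 6.92. These rates therefore hold for equal spread and may not hold for the real arrays. One simulated list of 20 genes was moved and called, and the other lists were not called. Simulated probe sets were drawn independently, so that run says nothing on lists whose genes move together. For the real list of oxidative phosphorylation and the TCA cycle, the estimated correlation between genes was 0.74.

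Python 3.11.15 with matplotlib 3.10.9 prepared the values and drew the plots. Probe sets without a gene symbol or with several symbols were counted and not named. Raw array images were not used here.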

Results

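The arrays covered the mouse heart from embryonic day E10.5 to E18.5 in C57BL/6 embryos. Ventricles and atria were separate samples at E12.5, E13.5, E14.5, E16.5 and E18.5, which made 10 groups. At E10.5 and E11.5 the samples were the middle part of the embryo that includes the heart, according to the description, while their source field names the whole heart. Each of the 12 groups had 3 arrays, and this number limits the precision. The values were intensities, already scaled to a 2% trimmed mean between 499.9 and 500.3 on each array. Correlations between arrays of a group were between 0.941 and 0.984. The labels do not say whether the 3 arrays came from separate animals, so the p-values measure the spread between samples.

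**Figure D1:**
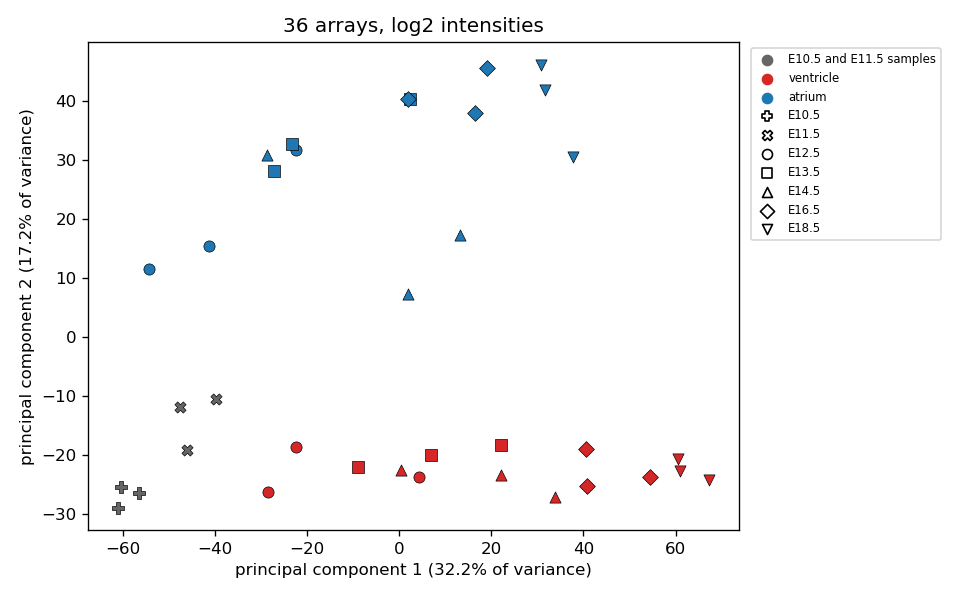
Principal components of log2 intensities, with 1 point per array, colour for the tissue and shape for the age. The first component held 32.2% of the variance and the second 17.2%, and atrial arrays had positive and ventricular arrays negative values on the second.

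The first comparison asked how atria and ventricles differed over the 5 ages, with 15 arrays of each. Sln, which encodes the calcium pump inhibitor sarcolipin, was 67.1-fold higher in atria (log2 6.07 ± 0.44 SE, adjusted p = 4.45e-12). Mybphl, a myosin binding protein family member, was 17.2-fold higher (4.10 ± 0.17). Irx4, a transcription factor known for its restriction to ventricles, was 15.8-fold lower in atria (-3.98 ± 0.37, adjusted p = 5.03e-10). Myoglobin, Mb, was 9.57-fold lower (-3.26 ± 0.33), and Hey2, a Notch target of the compact ventricular wall, 7.31-fold lower (-2.87 ± 0.25).

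Among the other genes with the largest differences, Fgf12 (4.57 ± 0.26), Vsnl1 (3.93 ± 0.14), Slit3 (3.35 ± 0.15), Pdlim4 (2.99 ± 0.16), Olfm1 (2.96 ± 0.17) and Mfap4 (2.85 ± 0.33) were higher in atria. Shox2, a regulator of the sinus node, was 9.94-fold higher (3.31 ± 0.19), and Nr2f1, a nuclear receptor of atrial muscle, 8.69-fold higher (3.12 ± 0.13). The potassium channel subunit gene Kcne1 was lower in atria (-3.66 ± 0.40), as were Ddc (-2.71 ± 0.24), Gtsf1 (-2.32), Upp1 (-2.27), Rbp7 (-2.25), Wif1 (-2.23) and Mpped2 (-2.16). In all, 11570 of 27256 probe sets differed, 5710 higher and 5860 lower in atria. Of these, 401 were at least 2-fold higher and 222 at least 2-fold lower. Under the strict filter the count for atrium against ventricle, mean of 5 ages was 7319.

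**Figure D2:**
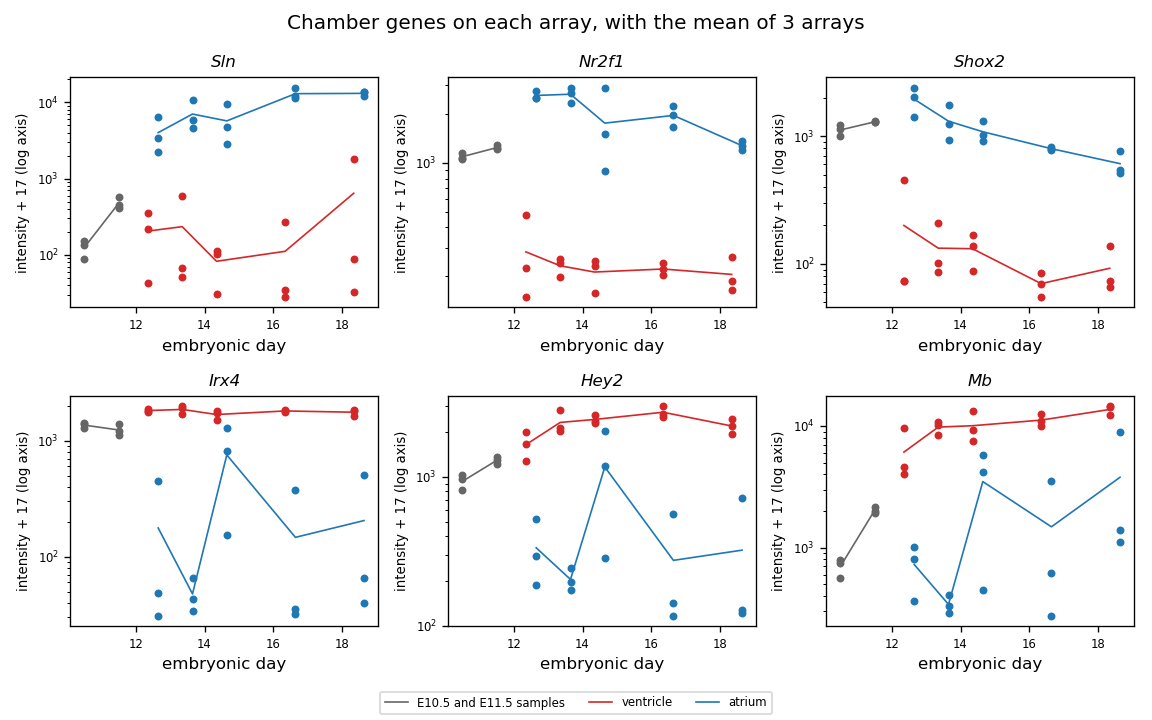
Intensity plus 17 on a log axis against embryonic day for 6 chamber genes, with 1 point per array and lines through the mean of 3 arrays. Atrial arrays lay above ventricular arrays for Sln, Nr2f1 and Shox2, while Irx4 reached 1281 on 1 atrial array of E14.5.

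Of 14 measured atrial chamber genes, 12 were higher in atria and 2 did not pass, with 13 higher when adjusted over the list alone (adjusted p = 3.1e-12; adjusted p = 0.028 with an estimated correlation). Examples were Tbx5, a T-box factor (1.81 ± 0.11), Stard10 (2.06), Angpt1 (1.97), the potassium channel gene Kcnj3 (1.90) and the connexin gene Gja5 (1.56). Nr2f2 (1.19) and the atrial myosin light chains Myl7 (0.84 ± 0.10) and Myl4 (0.22) were higher as well. At single ages Myl7 passed from E14.5 on. Myl4 passed at E16.5 and E18.5 alone, with 0.02, 0.09 and 0.08 at E12.5, E13.5 and E14.5. Nppa, the gene of atrial natriuretic peptide, had a difference of 0.18 (adjusted p = 0.0848). Its intensities lay near the top of the measured range, which limits what that value can show. Of 14 ventricular chamber genes, 13 were lower in atria and 1 did not pass, with 13 when adjusted over the list alone (adjusted p = 4.2e-11; adjusted p = 0.054 with an estimated correlation). Irx2 (-2.06 ± 0.14), the ventricular myosin light chains Myl2 (-1.95 ± 0.34) and Myl3 (-1.43) and the slow myosin heavy chain Myh7 (-1.90 ± 0.26) were among them.

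The muscle lists moved in both directions. Of 24 sarcomere genes, 4 were higher in atria, 11 lower and 9 not called, with 4 and 12 when adjusted over the list alone (adjusted p = 0.013; adjusted p = 0.61 with an estimated correlation). The list's call was lost under quantile normalization (adjusted p = 0.20) and with the mean of probe sets (adjusted p = 0.062). Myom2, an M-band protein, was higher (1.57), as was the heavy chain Myh6 (0.38), while Tnni1 (-0.15, adjusted p = 0.115) and Tnni3 (-0.12, adjusted p = 0.150) did not pass. From E12.5 to E18.5 Myom2 differed by 2.43, 2.25, 1.73, 1.14 and 0.30, and passed at E12.5 and E13.5 alone. Myh6 was called higher at each age up to E16.5, and was -0.14 (adjusted p = 0.56) at E18.5. Of 25 calcium handling and ion channel genes, 6 were higher and 9 lower, the same when adjusted over the list alone (adjusted p = 0.59), with a median of -0.08 and a mean of 0.14. Of 22 cardiac transcription factors, 6 were higher and 11 lower, with 7 and 11 when adjusted over the list alone (adjusted p = 0.95). Isl1, a factor of cardiac progenitors and the sinus node, was higher (2.22) and Nkx2-5, an early cardiac homeobox factor, lower (-0.18). Bmp10, a trabecular growth factor, was higher in atria (0.77 ± 0.17). Of 11 conduction system genes, 5 were higher and 1 lower, with 6 and 2 when adjusted over the list alone (adjusted p = 0.0056; adjusted p = 0.19 with an estimated correlation).

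Most genes of the metabolic lists were lower in atria. Of 30 genes of oxidative phosphorylation and the TCA cycle, 26 were lower and 4 did not pass, with 27 when adjusted over the list alone (adjusted p = 2e-09; adjusted p = 0.35 with an estimated correlation). Cox8b (-0.97), Cox7a1 (-0.47), Ogdh (-0.46) and Uqcrc1 (-0.40) were examples. Of 22 fatty acid oxidation genes, 15 were lower and 7 did not pass, with 16 when adjusted over the list alone (adjusted p = 7.6e-07; adjusted p = 0.27 with an estimated correlation), including Eci1 (-1.01), Fabp3 (-0.94), Acadvl (-0.72) and the nuclear receptor Ppara (-0.65). Of 19 glycolysis genes, 16 were lower and 2 higher, with 17 and 2 when adjusted over the list alone (adjusted p = 6.3e-08; adjusted p = 0.19 with an estimated correlation). The lactate transporter gene Slc16a3 (-1.28), Hk2 (-0.80) and Pfkp (-0.74) were among the lower ones. Of 10 hypoxia response genes, 7 were lower and 1 higher, the same when adjusted over the list alone (adjusted p = 0.00057; adjusted p = 0.26 with an estimated correlation). Vegfa (-0.85) and Ankrd37 (-0.84) were lower and Adm higher (0.78).

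Most genes of the epicardial and connective tissue lists were higher in atria. Of 12 epicardial genes, 11 were higher, with all 12 when adjusted over the list alone (adjusted p = 4.5e-09; adjusted p = 0.028 with an estimated correlation), including Aldh1a1 (2.39), Upk3b (1.91) and Upk1b (1.19). Of 20 fibroblast and matrix genes, 15 were higher and 5 did not pass, with 16 when adjusted over the list alone (adjusted p = 1.2e-06; adjusted p = 0.26 with an estimated correlation). Elastin, Eln (1.26), Lox (1.15), Fbln2 (1.03) and Mgp (0.87) were examples. Of 20 cushion and valve genes, 12 were higher and 2 lower, with 12 and 3 when adjusted over the list alone (adjusted p = 0.001; adjusted p = 0.23 with an estimated correlation), including the Notch ligand Jag1 (1.61), Bmp4 (1.30), Bmp2 (1.11) and Foxc2 (0.98). Of 13 macrophage and leukocyte genes, 8 were higher and 1 lower, with 9 and 1 when adjusted over the list alone (adjusted p = 0.011; adjusted p = 0.39 with an estimated correlation), including C1qa (1.15), the receptor gene Csf1r (0.83) and C1qc (0.77).

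The other lists gave fewer calls or mixed directions. Of 18 endothelial genes, 7 were higher and 6 lower, with 8 and 6 when adjusted over the list alone (adjusted p = 0.78), with a median of 0.04 and a mean of -0.02. Vwf (1.16) and Npr3 (0.84) were higher, and Fabp4 (-1.80) and Cldn5 (-0.84) lower. Of 6 smooth muscle genes, 3 were higher, with Tagln at 1.13, and 1 was lower, Acta2 at -0.30, the same when adjusted over the list alone (adjusted p = 0.35). Of 31 cell cycle genes, 10 were lower and 1 higher, with 9 and 0 when adjusted over the list alone (adjusted p = 0.038; adjusted p = 0.72 with an estimated correlation). Ccnd1 (-0.38) and Rrm2 (-0.31) were lower. Median centring ended this list's call (adjusted p = 0.088), and so did leaving out any of 9 single arrays, the highest being adjusted p = 0.12 without E13.5 atrial array 2. Of 14 immediate early and heat shock genes, 1 was higher, Fos (0.56), and 3 were lower, Nr4a1 (-0.68), Atf3 (-0.60) and Jun (-0.39), the same when adjusted over the list alone (adjusted p = 0.74). None of 4 sex-linked genes was called, nor any when adjusted over the list alone (adjusted p = 0.89).

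Lists of other tissues were measured in the same arrays. Of 6 adult erythroid genes, 3 were higher in atria, Alas2 (1.46), Slc4a1 (1.30) and Epb42 (1.22), the same when adjusted over the list alone (adjusted p = 0.075). Of 3 embryonic globin genes, Hba-x (0.86) and Hbb-y (0.74) were higher, with all 3 when adjusted over the list alone (adjusted p = 0.14). Of 10 liver genes, 3 were higher, with Ahsg at 2.11, Ttr at 1.28 and Rbp4 at 0.58, and 2 when adjusted over the list alone (adjusted p = 0.15). Rbp4 was 1.91 (adjusted p = 0.016) at E12.5, where atrial array 2 held high liver genes. At the later ages it was between -0.21 and 0.56 and did not pass. In the mean, Rbp4 lost its call without the 3 arrays with high lung genes (0.56, adjusted p = 0.088). Of 10 foregut and lung genes, 2 were higher, Foxa1 (1.18) and Cdh1 (0.99), and none when adjusted over the list alone (adjusted p = 0.86). Without the same 3 arrays Foxa1 was 0.58 (adjusted p = 0.18) and Cdh1 0.46 (adjusted p = 0.31). Of 10 neural genes, 1 was higher, Elavl4 (0.42), and 2 lower, Elavl3 (-0.88) and Mapt (-0.40), the same when adjusted over the list alone (adjusted p = 0.97), with a median of 0.08 and a mean of -0.04. Of 7 somite and skeletal muscle genes, Myh8 was higher (0.99) and Meox2 lower (-1.09), the same when adjusted over the list alone (adjusted p = 0.89). The thymus and brown fat lists had 2 measured genes each and were not tested. No thymus gene was called, while Cebpa was higher (1.05) and Cidea lower (-1.17) among the brown fat genes.

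At single ages the same comparison, with 3 arrays a chamber, gave 2637 probe sets at E12.5, 3310 at E13.5, 1684 at E14.5, 4600 at E16.5 and 5314 at E18.5. Sln differed at each age, by 4.61, 5.70, 6.16, 7.65 and 6.24 (each ± 0.99). So did Mybphl, by 2.85, 4.31, 3.45, 5.14 and 4.77 (each ± 0.37), Nr2f1, by 3.37, 3.52, 2.91, 3.14 and 2.66 (each ± 0.29), and Tbx5, by 1.20, 1.69, 1.04, 2.54 and 2.56 (each ± 0.25). Tbx5 had adjusted p = 0.011 at E14.5, and adjusted p = 0.093 and adjusted p = 0.10 there without atrial array 3 or ventricular array 1, and with the 6 arrays alone adjusted p = 0.089 at E12.5 and adjusted p = 0.20 at E14.5. With the mean of probe sets Tbx5 had adjusted p = 0.083 at E12.5 and adjusted p = 0.051 at E14.5. Bmp10 differed by -0.24, 0.78, -0.47, 1.68 and 2.08 from E12.5 to E18.5 (each ± 0.38) and passed at E16.5 and E18.5 (adjusted p = 0.0022 and adjusted p = 0.00018), while at E12.5 and E14.5 it had adjusted p = 0.76 and adjusted p = 0.49 with the opposite sign. Jag1 was higher in atria at each age, by between 1.46 and 1.77 (each ± 0.14). Isl1 differed by 2.38, 2.53, 3.28, 1.63 and 1.29 (each ± 0.52) and passed at all ages but E18.5 (adjusted p = 0.08), with adjusted p = 0.055 at E12.5, adjusted p = 0.059 at E14.5 and adjusted p = 0.14 at E16.5 in fits of the 6 arrays alone. At E16.5 the call of Isl1 (adjusted p = 0.029) was lost without any 1 of 5 arrays and in other settings, with 0.92 (adjusted p = 0.25) without atrial array 2, while at E18.5 Isl1 passed without atrial array 3 (adjusted p = 0.023). Irx4 differed by -4.36, -5.33, -1.62, -4.59 and -4.0 (each ± 0.82) and Hey2 by -2.40, -3.50, -1.46, -3.68 and -3.30 (each ± 0.55). At E14.5 neither passed (adjusted p = 0.24 and adjusted p = 0.11), with Hey2 at -2.07 (adjusted p = 0.03) without atrial array 1, and intensities of Irx4 on the 3 atrial arrays were 1281, 792 and 137. Irx4 had adjusted p = 0.055 at E12.5 with the 6 arrays alone.

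Vwf, of endothelium, was higher in atria at each age, by 0.91, 1.43, 1.04, 1.29 and 1.14 (each ± 0.20), with adjusted p = 0.053 at E12.5 without ventricular array 2, and adjusted p = 0.15 at E12.5 and adjusted p = 0.096 at E14.5 in fits of the 6 arrays alone. Npr3 differed by 0.27, 0.63, 0.26, 1.27 and 1.77 (each ± 0.15) and passed at E13.5, E16.5 and E18.5, and at E14.5 without atrial array 1 (0.54, adjusted p = 0.0094). Csf1r, of macrophages, differed by 0.48, 0.78, 0.73, 1.03 and 1.12 (each ± 0.21) and passed from E13.5 on (adjusted p = 0.011 at E13.5 and adjusted p = 0.031 at E14.5), and at E12.5 without atrial array 1 (0.75, adjusted p = 0.033). The call of Csf1r was lost at E13.5 without atrial array 3 (adjusted p = 0.058), ventricular array 1 (adjusted p = 0.06) or ventricular array 2 (adjusted p = 0.05), and at E14.5 without any 1 of 4 arrays, with adjusted p = 0.20 without atrial array 3, and at both ages in other settings too, with 0.23 (adjusted p = 0.43) at E14.5 for the mean of probe sets. C1qa differed by 1.21, 0.74, 1.18, 1.12 and 1.49 (each ± 0.41) and passed at E18.5 alone (adjusted p = 0.0086), and at E12.5 without ventricular array 2 (1.85, adjusted p = 0.0031) or atrial array 1 (adjusted p = 0.031), and at each earlier age in at least 1 other setting.

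Lists at single ages had the same direction as in the mean for the chamber genes. Atrial chamber genes were higher for 9, 9, 10, 12 and 12 of 14 members from E12.5 to E18.5, and ventricular chamber genes lower for 11, 13, 4, 11 and 10 of 14. When adjusted over the list alone these were 10, 11, 11, 13 and 12 for the atrial list and 12, 13, 9, 12 and 14 for the ventricular one, and 1 atrial gene was lower at E16.5 and 1 at E18.5. At E14.5 the called ventricular genes numbered 2, 1 and 0 without ventricular array 1, ventricular array 3 or atrial array 3, and the called atrial genes 6 and 5 without ventricular array 1 or atrial array 3. At E16.5, 7 ventricular genes were called without atrial array 1 or 3. The atrial list kept adjusted p = 0.032 or less with an estimated correlation up to E16.5, and at E18.5 had adjusted p = 0.056 with an estimated correlation. With an estimated correlation, the atrial list's call at E12.5 was lost without atrial array 3 of that age (adjusted p = 0.064). Its call at E14.5 was lost without ventricular array 3 (adjusted p = 0.067) or atrial array 2 (adjusted p = 0.07) of that age. The ventricular list had adjusted p = 0.14 with an estimated correlation from E14.5 on, with adjusted p = 8.4e-07 at E14.5 with the preset one. Cushion and valve genes were higher for 7 of 20 at E14.5 (adjusted p = 9.2e-07; adjusted p = 0.044 with an estimated correlation), with 9 when adjusted over the list alone. The score of that list, its mean log2 value minus the mean over the 36 arrays, was 0.84 on E14.5 atrial array 1 against 0.08 and 0.24 on arrays 2 and 3. Without array 1, 3 of these genes were higher (adjusted p = 0.0024; adjusted p = 0.13 with an estimated correlation), and without ventricular array 1 also 3. Without ventricular array 1 or 3 the list had adjusted p = 0.056 and adjusted p = 0.091 with an estimated correlation. At E18.5, 18 of 30 genes of oxidative phosphorylation and the TCA cycle were lower in atria, with 25 when adjusted over the list alone (adjusted p = 4.7e-11; adjusted p = 0.34 with an estimated correlation).

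Single arrays moved the number of probe sets at each age: it was 1228 without E12.5 atrial array 1, 1986 without E13.5 ventricular array 1, 545 and 564 without E14.5 atrial array 3 or ventricular array 1, 3065 without E16.5 ventricular array 3, and 3507 without E18.5 atrial array 3. Without the 3 atrial arrays with high lung genes (array 3 of E13.5, E16.5 and E18.5), the counts were 2198 for atrium against ventricle at E13.5 and 3454 for atrium against ventricle at E18.5. In settings that left out no array of the compared groups, the count was between 279 and 6994 for atrium against ventricle at E12.5 and between 29 and 2275 for atrium against ventricle at E14.5.

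**Figure D3:**
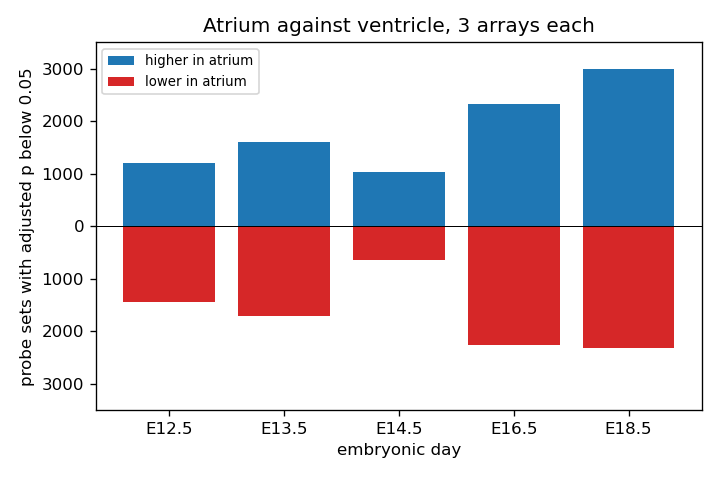
Number of probe sets higher (above 0) and lower (below 0) in atrium than in ventricle at each age, with 3 arrays of each chamber. The counts were lowest at E14.5, with 1036 higher and 648 lower, and highest at E18.5, with 2990 and 2324.

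The next comparison asked what changed in the ventricle over the period of isolated chambers, from E12.5 to E18.5, with 3 arrays at each age. Myom2, an M-band gene of mature sarcomeres, rose 48.2-fold (log2 5.59 ± 0.66, adjusted p = 5.27e-07). Kcnip2, a subunit of the transient outward potassium channel, rose 27.5-fold (4.78 ± 0.58), and Ckmt2, the mitochondrial creatine kinase, 18.5-fold (4.21 ± 0.39). The embryonic globin genes Hbb-bh1 (-7.79 ± 1.30), Hba-x (-7.01 ± 0.50) and Hbb-y (-5.92 ± 0.36) fell, as did Hapln1, a link protein of the cardiac jelly (-3.30 ± 0.53).

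Other large increases were in Dhrs7c (4.74 ± 0.69), Aoc3 (4.01 ± 0.60), Ptgds (3.96 ± 0.64), Rgs5 (3.96 ± 0.64), Nmrk2 (3.87 ± 0.47), Adhfe1 (3.68 ± 0.41) and Fabp4 (3.67 ± 0.76). Slc4a1 (-4.14 ± 0.72), Col2a1 (-3.50 ± 0.63), Npnt (-3.38 ± 0.30), Igfbp2 (-3.23 ± 0.30), Rec8 (-3.18 ± 0.34) and Hmga2 (-3.13 ± 0.41) fell. The transcription factor genes Gata5 (-3.06 ± 0.27) and Gata6 (0.66) moved in opposite directions. In all, 7835 probe sets changed, 3468 higher and 4367 lower at E18.5, with 789 and 816 at least 2-fold.

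In the lists of energy metabolism more genes rose than fell in the ventricle. Of 22 fatty acid oxidation genes, 18 rose and 4 did not pass, the same when adjusted over the list alone (adjusted p = 1.6e-10; adjusted p = 0.41 with an estimated correlation). Cd36, a fatty acid transporter (2.16 ± 0.24), Ppara (1.95), Acadvl (1.05) and Fabp3 (1.03) were examples. Of 30 genes of oxidative phosphorylation and the TCA cycle, 16 rose and 14 did not pass, with 18 when adjusted over the list alone (adjusted p = 1.5e-07; adjusted p = 0.65 with an estimated correlation), including Cox8b (2.77 ± 0.42), Cox7a1 (1.36) and Cox6a2 (0.73). Of 10 hypoxia response genes, 8 rose, the same when adjusted over the list alone (adjusted p = 0.00023; adjusted p = 0.48 with an estimated correlation), including Egln3 (2.51) and Ndrg1 (1.74). Of 19 glycolysis genes, 7 rose and 2 fell, with 8 and 3 when adjusted over the list alone (adjusted p = 0.11). The insulin-responsive glucose transporter gene Slc2a4 rose (1.33), as did Eno3 (1.03) and Pfkm (0.85), while the ubiquitous transporter gene Slc2a1 fell (-1.11).

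Of the cell cycle and cushion genes, more fell than rose in the ventricle. Of 31 cell cycle genes, 12 fell and 1 rose, with 13 and 1 when adjusted over the list alone (adjusted p = 0.00057; adjusted p = 0.65 with an estimated correlation), including Tyms (-1.31), Mcm3 (-0.76) and Mcm5 (-0.64). Without E12.5 or E18.5 ventricular array 3, 7 and 6 of them fell. Of 20 cushion and valve genes, 10 fell and 2 rose, with 11 and 2 when adjusted over the list alone (adjusted p = 0.0079; adjusted p = 0.60 with an estimated correlation), including Vcan (-1.53) and Twist1 (-1.46). Of 20 fibroblast and matrix genes, 12 rose and 3 fell, with 13 and 3 when adjusted over the list alone (adjusted p = 0.0019; adjusted p = 0.65 with an estimated correlation), including Dpt (3.60), Postn (1.49), Mgp (1.40) and Col1a1 (1.31). All 3 embryonic globin genes fell, the same when adjusted over the list alone (adjusted p = 9.1e-06; adjusted p = 0.023 with an estimated correlation).

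Contractile and channel genes moved in both directions. Of 24 sarcomere genes, 8 rose and 3 fell, the same when adjusted over the list alone (adjusted p = 0.15), with Myh6 (0.59 ± 0.15) and Tnni3 (0.56 ± 0.15) higher at E18.5. The atrial light chains Myl7 (-1.06 ± 0.21) and Myl4 (-0.68 ± 0.15) fell. Of 25 calcium handling and ion channel genes, 7 rose and 4 fell, the same when adjusted over the list alone (adjusted p = 0.097), including Cacna1g (3.06 ± 0.36), Kcnq1 (1.68) and Casq2 (1.53), which rose, and Gja5 (-1.80), which fell. Of 18 endothelial genes, 7 rose and 4 fell, with 8 and 5 when adjusted over the list alone (adjusted p = 0.51), with Aqp1 at 1.81, Cldn5 at 1.58 and Plvap at -1.20. Of 12 epicardial genes, 6 fell and 1 rose, with 6 and 2 when adjusted over the list alone (adjusted p = 0.17), with Krt19 at -1.72 and Aldh1a1 at -1.69. Among the heart genes given in each comparison, those that did not pass included Nppa (-0.42, adjusted p = 0.0940), Tbx5 (-0.64, adjusted p = 0.054), Hey2 (0.43) and Sln (0.22). No liver gene was called (adjusted p = 0.59), nor any of the 10 foregut and lung genes (adjusted p = 0.70), nor any of either when adjusted over the list alone.

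**Figure D4:**
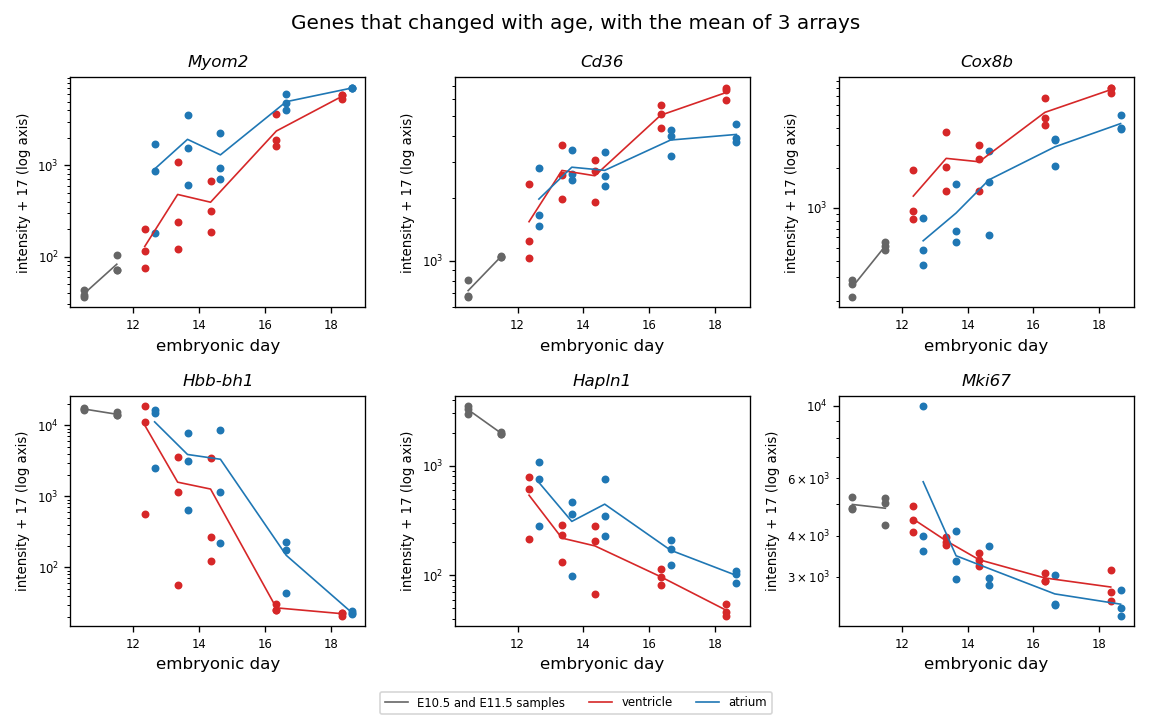
Intensity plus 17 on a log axis against embryonic day for 6 genes, with 1 point per array and lines through the mean of 3 arrays. Myom2, Cd36 and Cox8b were higher and Hbb-bh1, Hapln1 and Mki67 lower at E18.5 than at E12.5 in both chambers.

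The same question in the atrium, from E12.5 to E18.5 with 3 arrays at each age, gave 6610 probe sets, 3426 higher and 3184 lower at E18.5. Aspn, which encodes the matrix protein asporin, rose 19.1-fold (log2 4.25 ± 0.57, adjusted p = 8.14e-06), and Dpt, the gene of dermatopontin, 19.3-fold (4.27 ± 0.74). Tpsb2, a mast cell tryptase, rose 11.2-fold (3.49 ± 0.50), and Myom2 rose by 3.46 ± 0.66. Hbb-bh1 (-8.53 ± 1.30), Hba-x (-5.97 ± 0.50) and the red cell genes Slc4a1 (-4.91 ± 0.72), Kel (-4.52 ± 0.73) and Hemgn (-4.62 ± 0.82) fell.

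Further increases were in Dhrs7c (3.77 ± 0.69), Aoc3 (3.35 ± 0.60), Cp (3.33 ± 0.41), the muscle creatine kinase Ckm (3.28 ± 0.76), Cox8b (3.01 ± 0.42) and Bmp10 (1.86 ± 0.38). Scgb3a2, a secretoglobin of airway epithelium, rose as well (3.66 ± 0.68), as did Ahsg, a plasma protein gene of liver (3.47 ± 0.79). Scgb3a2 intensities on the 3 atrial arrays of E18.5 were 1455, 3021 and 7232. Without the arrays with high lung genes, Scgb3a2 was 3.06 (adjusted p = 0.0035) and Ahsg 3.30 (adjusted p = 0.011). The lung surfactant gene Sftpc was 3.04, and 1.30 (adjusted p = 0.36) without E18.5 atrial array 3, on which its intensity was 10949. Epb42 (-4.24 ± 0.82), Ermap (-4.22 ± 0.73), Nfe2 (-3.89 ± 0.70) and Hapln1 (-2.63) fell. Shox2 (-1.67), Tbx18 (-1.11), Nr2f1 (-1.03) and the skeletal actin gene Acta1 (-1.89) fell too. Sln (1.85 ± 0.99, adjusted p = 0.183), Nppa (-0.20), Myh6 (-0.14), Myl4 (-0.22), Myl7 (-0.22) and Tnni3 (0.35, adjusted p = 0.0870) did not pass.

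Of 31 cell cycle genes, 24 fell in the atrium and 7 did not pass, with 28 when adjusted over the list alone (adjusted p = 1.4e-12; adjusted p = 0.17 with an estimated correlation). Without E12.5 atrial array 1, 15 fell (adjusted p = 5.4e-09). The score of the cell cycle list, its mean log2 value minus the mean over the 36 arrays, was 0.55 on that array against 0.07 and 0.01 on arrays 2 and 3, and the score of the adult erythroid list was 3.39 against 2.09 and 0.25. Mcm5 (-0.81) was an example, while Mki67 (-1.09) and Cdc6 (-1.01) lost their calls in a fit of the 6 arrays alone (adjusted p = 0.066 and adjusted p = 0.052). Of 20 fibroblast and matrix genes, 15 rose and 2 fell, with 17 and 2 when adjusted over the list alone (adjusted p = 6.8e-06; adjusted p = 0.27 with an estimated correlation), including Eln (2.09), Mgp (1.77) and Postn (1.69), while 7 rose without E12.5 atrial array 1 and 9 without E18.5 atrial array 3. Of 18 endothelial genes, 9 rose and none fell, with 11 when adjusted over the list alone (adjusted p = 2e-06; adjusted p = 0.099 with an estimated correlation), including Cd34 (1.78), Eng (1.42) and Aqp1 (1.36). Of 13 macrophage and leukocyte genes, 8 rose, with 10 when adjusted over the list alone (adjusted p = 9.7e-05; adjusted p = 0.20 with an estimated correlation), including C1qa (1.96), Cd14 (1.51) and C1qc (1.15). Of 22 fatty acid oxidation genes, 13 rose, the same when adjusted over the list alone (adjusted p = 2.8e-05; adjusted p = 0.42 with an estimated correlation), including Ppara (1.68), Cd36 (1.09) and Fabp3 (0.91). Of 30 genes of oxidative phosphorylation and the TCA cycle, 5 rose, the same when adjusted over the list alone (adjusted p = 0.11).

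All 6 adult erythroid genes fell in the atrium, the same when adjusted over the list alone (adjusted p = 8.2e-06; adjusted p = 0.17 with an estimated correlation), including Klf1 (-3.42), and so did all 3 embryonic globin genes, the same when adjusted over the list alone (adjusted p = 4.4e-06; adjusted p = 0.017 with an estimated correlation). Of 10 hypoxia response genes, 6 rose, with 8 when adjusted over the list alone (adjusted p = 0.00013; adjusted p = 0.21 with an estimated correlation), including Egln3 (2.15), Adm (1.38) and Vegfa (1.06). Of 14 immediate early and heat shock genes, 6 rose, the same when adjusted over the list alone (adjusted p = 0.011; adjusted p = 0.17 with an estimated correlation), including Fos (1.20) and Egr1 (1.11). Meox1 (2.14), Meox2 (2.15) and Myh8 (2.16) of the somite and skeletal muscle list rose, the same when adjusted over the list alone (adjusted p = 0.35), and so did both brown fat genes, with Cidea at 2.67. Of 10 liver genes, 4 fell and 1 rose, with 5 and 1 when adjusted over the list alone (adjusted p = 0.16), with Afp at -4.84 ± 1.75, and at -3.99 (adjusted p = 0.12) without the arrays with high liver genes. Without E12.5 atrial array 1 the count for the atrium was 3817, a fit of the 6 arrays alone gave 4051, and array weights gave 12642 for atrium, E18.5 against E12.5. In that last setting E12.5 atrial array 2, with high liver genes, had a weight of 6.92, against 0.28 and 0.51 for arrays 1 and 3.

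Between the chambers, the changes from E12.5 to E18.5 had much in common. Of the probe sets, 1754 rose in both chambers against 435.9 expected for independent calls, 1543 fell in both against 510.1, and 124 were called in opposite directions. The correlation of the log2 changes across probe sets, which are not independent replicates, was 0.62.

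The difference between chambers in the change from E12.5 to E18.5 was tested directly, and 1030 probe sets differed, 724 with the more positive change in atrium and 306 with the more negative. Tmem100, a target of BMP signalling in endothelium, changed by 2.67 ± 0.32 more in the atrium (adjusted p = 7.41e-06). Tgfbi (2.65 ± 0.41), Sall1 (2.63 ± 0.33), and Hdc, the histidine decarboxylase of mast cells (2.70), differed in the same direction. The channel genes Kcna5 (-2.80 ± 0.42, adjusted p = 2.20e-04) and Cacna1g (-2.66 ± 0.51) changed more positively in the ventricle, as did Tuba4a (-2.00 ± 0.35) and Rtl3 (-2.59 ± 0.57). Lyz1 (3.52 ± 0.47) and Lyz2 (2.29) were 2.84 (adjusted p = 2.4e-05) and 1.70 (adjusted p = 9e-04) without the arrays with high lung genes.

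Gata5 (2.12), Angpt1 (1.95), Krt19 (2.28), Fbln1 (1.26), Fos (1.23) and Myh8 (2.16) had the more positive change in the atrium, and Hey1 (-1.13) and the retinoic acid synthesis gene Aldh1a2 (-1.03) in the ventricle. Bmp10 differed by 2.32 ± 0.54, and did not pass without E12.5 atrial array 1 (adjusted p = 0.058). Of 18 endothelial genes, 7 had the more positive change in the atrium, with 10 when adjusted over the list alone (adjusted p = 8.6e-05; adjusted p = 0.51 with an estimated correlation). Eng (1.32) and Plvap were among them, and 4 were called without E12.5 atrial array 1, E12.5 ventricular array 1, E18.5 atrial array 2 or 3, or E18.5 ventricular array 2. Eng had adjusted p = 0.057 in a fit of the compared arrays alone, and Plvap was 1.33 (adjusted p = 0.051) under median centring. Of 20 cushion and valve genes, 4 had it, the same when adjusted over the list alone (adjusted p = 0.0078; adjusted p = 0.70 with an estimated correlation), and with any one of the same arrays left out, 1 or 2 had it. No gene of oxidative phosphorylation and the TCA cycle was called, nor any when adjusted over the list alone, while the list had a median of -0.24 (adjusted p = 8.6e-05; adjusted p = 0.70 with an estimated correlation; adjusted p = 0.068 under quantile normalization). The liver, adult erythroid and macrophage lists had medians of -1.51, -1.50 and 0.39, with 0, 0 and 1 genes called. Each had adjusted p = 0.017, and adjusted p = 0.70 with an estimated correlation. At an unadjusted p below 0.05 there were 4993 probe sets in all. The count for difference between chambers in the change from E12.5 to E18.5 was 452, 2014, 579, 481, 514 and 560 without E12.5 atrial array 1, E12.5 atrial array 3, E12.5 ventricular array 1, E18.5 atrial array 2, E18.5 atrial array 3 and E18.5 ventricular array 2. It was 490 without the arrays with high lung genes, 425 with median centring, 407 with the compared arrays alone and 4733 with array weights.

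Shorter intervals separated the days that the labels tie to septation, E12.5 to E14.5, from later growth. In the ventricle, 17 probe sets changed from E12.5 to E14.5, 2 higher and 15 lower, and 4397 had an unadjusted p below 0.05. The glutamate transporter gene Slc1a3 (-1.61 ± 0.31) and the peptidase gene Anpep (-1.31 ± 0.26) fell and Ggact rose (0.97 ± 0.19), each with adjusted p = 0.047 and adjusted p = 0.062 without a filter. The count for ventricle, E14.5 against E12.5 was 4, 851 and 0 without E12.5 ventricular array 1, 2 or 3 and 0 and 386 without E14.5 ventricular array 1 or 2. It was 0 without a filter, without the trend, with a pseudocount of 68, with the replicate number as a block and with the 6 arrays alone, and 366 with array weights.

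From E14.5 to E18.5, 3791 probe sets changed in the ventricle. Kcnip2 (4.48 ± 0.58), Myom2 (4.06 ± 0.66), Ckmt2 (3.34 ± 0.39), Cox8b (1.88 ± 0.42) and Cd36 (1.36 ± 0.24) rose, and Hba-x (-5.84 ± 0.50), Hbb-y (-5.66 ± 0.36), Npnt (-2.65 ± 0.30), Igfbp2 (-2.54 ± 0.30) and Gata5 (-2.43 ± 0.27) fell. Of 22 fatty acid oxidation genes, 12 rose, with 16 when adjusted over the list alone (adjusted p = 5.6e-08; adjusted p = 0.76 with an estimated correlation). Of 30 genes of oxidative phosphorylation and the TCA cycle, 10 rose, with 14 when adjusted over the list alone (adjusted p = 4.4e-07; adjusted p = 0.82 with an estimated correlation). Without E14.5 ventricular array 2, 6 fatty acid oxidation genes and 4 of the oxidative list rose, and without E18.5 ventricular array 1 or 2, 6 and 5 of the oxidative list. The count for ventricle, E18.5 against E14.5 was 2037 without E14.5 ventricular array 2, 2226 without E18.5 ventricular array 2 and 2062 with the 6 arrays alone.

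In the atrium, 539 probe sets changed from E12.5 to E14.5, 309 higher and 230 lower. The red cell genes Hemgn (-3.36 ± 0.82), Kel (-3.08 ± 0.73) and Klf1 (-2.60 ± 0.62) fell, and Meox1 (2.31 ± 0.49) and the Wnt modulator gene Sfrp2 (1.88 ± 0.39) rose. Without E12.5 atrial array 1 these were Hemgn -2.21 (adjusted p = 0.43), Kel -2.35 (adjusted p = 0.39), Klf1 -1.46 (adjusted p = 0.43), Meox1 2.06 (adjusted p = 0.27) and Sfrp2 1.38 (adjusted p = 0.28). Without E14.5 atrial array 1, Meox1 was 1.49 (adjusted p = 0.22) and Sfrp2 1.43 (adjusted p = 0.20). Of 20 fibroblast and matrix genes, 5 rose, with 17 higher and 1 lower when adjusted over the list alone (adjusted p = 2e-09; adjusted p = 0.23 with an estimated correlation). Their number was 0, 1 and 13 without E12.5 atrial array 1, 2 or 3 and 0, 0 and 12 without E14.5 atrial array 1, 2 or 3. No ventricular chamber gene was called, while the median of that list was 0.79, with 8 higher when adjusted over the list alone (adjusted p = 0.00049; adjusted p = 0.28 with an estimated correlation). The score of the ventricular list, its mean log2 value minus the mean over the 36 arrays, was 0.21, 0.34 and -0.97 on E14.5 atrial arrays 1, 2 and 3, and -1.33, -0.25 and -1.38 on those of E12.5. Without E14.5 atrial array 1, 2 or 3 the median was 0.66 (adjusted p = 0.0015), 0.54 (adjusted p = 0.036) and 1.22 (adjusted p = 1.6e-06), with 0, 0 and 7 genes called, and without E12.5 atrial array 2 or 3, 2 and 1 were called. The count for atrium, E14.5 against E12.5 was 0, 306 and 2290 without E12.5 atrial array 1, 2 or 3 and 0, 146 and 1919 without E14.5 atrial array 1, 2 or 3. It was 0 with the 6 arrays alone, 226 without the arrays with high liver genes, 236 with median centring, 317 without a filter, 337 without the trend and 1924 with array weights.

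From E14.5 to E18.5, 1956 probe sets changed in the atrium. Tpsb2 (2.65 ± 0.50), Dmkn (2.48 ± 0.30), Tmem100 (2.15 ± 0.23) and Eng (0.88 ± 0.18) rose, and Hba-x (-5.26 ± 0.50), Hbb-y (-4.04 ± 0.36) and Hmga2 (-2.48 ± 0.41) fell. Of 18 endothelial genes, 7 rose, with 12 when adjusted over the list alone (adjusted p = 6e-08; adjusted p = 0.044 with an estimated correlation). Without any one of the 6 arrays the list had adjusted p = 0.052 to 0.099 with an estimated correlation. The count for atrium, E18.5 against E14.5 was 1069, 1070 and 1090 without E14.5 atrial array 3 or E18.5 atrial arrays 2 and 3. It was 1076 without the arrays with high lung genes, 1187 with median centring and 807 with the 6 arrays alone.

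From E10.5 to E11.5, in the middle part of the embryo with 3 arrays at each age, 315 probe sets changed, 253 higher and 62 lower. C1qc, a complement gene of macrophages, rose 7.63-fold (2.93 ± 0.27, adjusted p = 2.13e-07), and Fbln5, an elastic fibre protein, 11.1-fold (3.47 ± 0.60). Sfrp2 (2.69 ± 0.39), the adult globin gene Hbb-b2 (2.64 ± 0.46), Mgp (2.09 ± 0.35), the transcription factor gene Nfix (2.09 ± 0.34), Kcne3 (1.99 ± 0.35), Lox (1.96 ± 0.29) and Lum (1.82 ± 0.26) rose. Nolc1, a nucleolar protein gene, fell (-0.62 ± 0.10).

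Of 13 macrophage and leukocyte genes, 4 rose, with 9 when adjusted over the list alone (adjusted p = 8.6e-13; adjusted p = 0.023 with an estimated correlation), including Adgre1 (0.95 ± 0.17), with 2 called without E11.5 array 1 or 2. Of 20 fibroblast and matrix genes, 6 rose, with 13 when adjusted over the list alone (adjusted p = 1.9e-11; adjusted p = 0.20 with an estimated correlation), with 3 called without E10.5 array 3 or E11.5 array 2. The sarcomere gene Myoz2 rose (1.09 ± 0.18). No cell cycle gene was called, with 1 lower when adjusted over the list alone, while the median of the 31 genes was -0.16 (adjusted p = 2.3e-06; adjusted p = 0.65 with an estimated correlation). The heart genes given in each comparison did not pass, with values from -0.45 to 1.95 and a lowest adjusted p of 0.433. At an unadjusted p below 0.05 there were 3347 probe sets. The count for middle part of the embryo, E11.5 against E10.5 was 204, 177 and 67 without E10.5 array 1, 2 or 3 and 137 and 61 without E11.5 array 1 or 2. It was 2218 with the 6 arrays alone, 2417 with array weights and 123 with median centring.

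**Figure D5:**
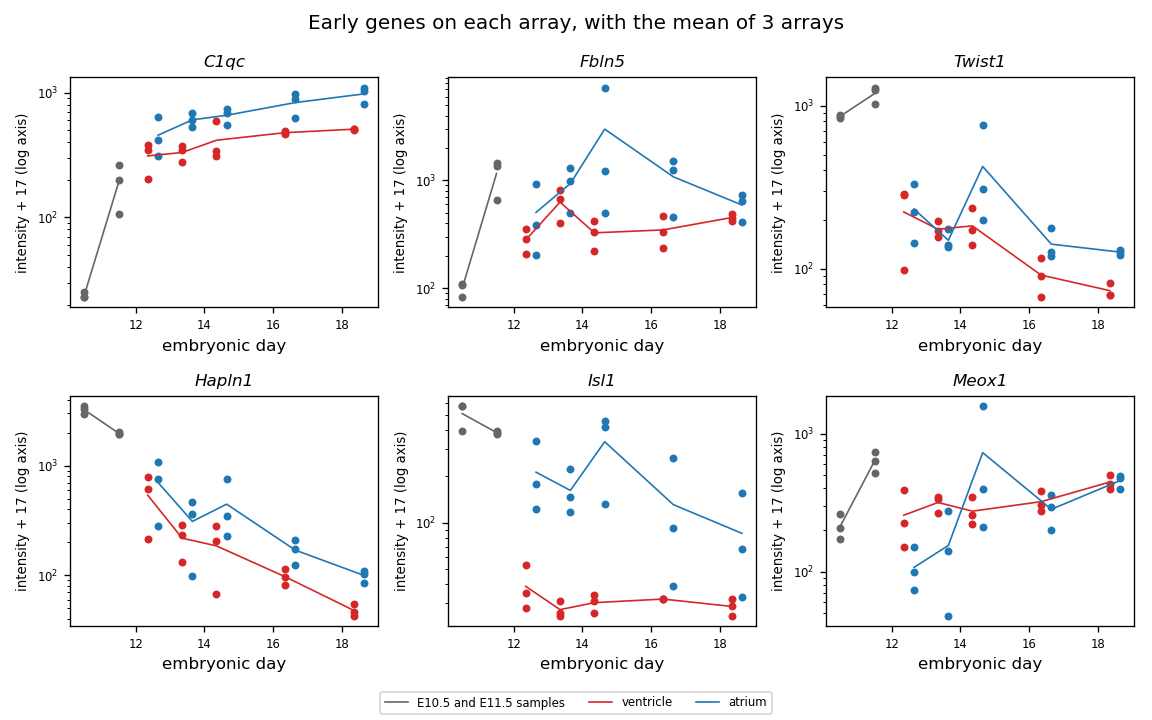
Intensity plus 17 on a log axis against embryonic day for 6 genes, with 1 point per array and lines through the mean of 3 arrays. C1qc and Fbln5 rose from E10.5 to E11.5, and Twist1 was lower in both chambers at E12.5 than at E11.5.

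The last comparison set the isolated heart at E12.5, as the mean of both chambers (6 arrays), against the middle part of the embryo at E11.5 (3 arrays), so that age and dissection changed together. Twist1, a factor of cushion mesenchyme, was 5.63-fold lower in the isolated heart (-2.49 ± 0.31, adjusted p = 6.02e-05), and the cartilage collagen gene Col9a3 8.58-fold lower (-3.10 ± 0.45). Cthrc1 (-2.46 ± 0.37), Papss2 (-2.12 ± 0.30) and the hyaluronan synthase gene Has2 (-1.75 ± 0.27) were lower, and Tnxb (2.11 ± 0.26) and Ifi27l2a (1.86 ± 0.26) higher. In all, 255 probe sets differed, 74 higher and 181 lower, and 3447 had an unadjusted p below 0.05.

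Of 20 cushion and valve genes, 9 were lower in the isolated heart and 11 did not pass, with 14 when adjusted over the list alone (adjusted p = 3.6e-17; adjusted p = 0.0011 with an estimated correlation). Without E11.5 array 1, 2 or 3, 4, 3 and 4 were lower. Of 13 macrophage and leukocyte genes, 5 were higher, with 9 when adjusted over the list alone (adjusted p = 7.7e-09; adjusted p = 0.063 with an estimated correlation), and 3, 1 and 1 without E11.5 array 1, 2 or 3, 3 without E12.5 atrial array 3 and 2 without E12.5 ventricular array 2. Of 11 conduction system genes, 2 were lower, with 6 when adjusted over the list alone (adjusted p = 0.00053; adjusted p = 0.072 with an estimated correlation), with 0, 0 and 1 lower without E11.5 array 1, 2 or 3, and array weights gave adjusted p = 0.16. Isl1 was one of them (-2.18 ± 0.45), and its adjusted p was 0.075 and 0.076 without E11.5 array 1 or 2. Of 22 cardiac transcription factor genes, 1 was lower, with 3 when adjusted over the list alone, and the median was -0.17 (adjusted p = 0.0073; adjusted p = 0.34 with an estimated correlation). Without E12.5 atrial array 1 that list had adjusted p = 0.084, with array weights adjusted p = 0.21 and under the strict filter adjusted p = 0.20, and 0 genes were called without each E11.5 array and 2 without E12.5 atrial array 2. Of 14 ventricular chamber genes none was called, with 1 lower when adjusted over the list alone, and the median was -0.46 (adjusted p = 0.0031; adjusted p = 0.64 with an estimated correlation; adjusted p = 0.30 with array weights). No neural gene (adjusted p = 0.95), liver gene (adjusted p = 0.17) or foregut and lung gene (adjusted p = 0.95) was called, and 1 of 7 somite genes was lower, with a list median of 0.46 (adjusted p = 0.52). The heart genes given in each comparison were not called, with values from -1.62 to 0.65 and a lowest adjusted p of 0.330. The count for isolated heart at E12.5 against middle part of the embryo at E11.5 was 79, 40 and 80 without E11.5 array 1, 2 or 3. It was 165 with median centring, 114 with the compared arrays alone and 2907 with array weights.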

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

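Of the tests in this part, those of a wrong chamber label, of cushion tissue at E14.5 and of both explanations for the E11.5 samples were chosen only after the result was seen, as were the fits without arrays with high lung or liver genes and the sorting of the other splits by what they mixed.

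Some atrial arrays held ventricular genes at high levels, most of all at E14.5, with Irx4 at 1281 on array 1, 792 on array 2 and 137 on array 3. A scale from 0 (ventricle) to 1 (atrium) was set with genes at least 4-fold apart at E13.5 and E16.5 (19 ventricular, 26 atrial). Ranges in parentheses came from resampling these genes as if they were independent. They hold no spread between samples. The position on ventricular genes was 0.29 and 0.59 on E14.5 atrial arrays 1 and 2. It was also 0.76 (0.51 to 0.81) on E18.5 atrial array 1 and 0.84 (0.69 to 0.94) on E16.5 atrial array 2. There the position on atrial genes was 0.15 (-0.15 to 0.48) and 0.06 (-0.09 to 0.24) higher, which leaves their cause open. The E16.5 array was itself among those that set the atrial end of the scale, which draws its position towards 1. That E14.5 array 1 was a wrongly labelled ventricular sample free of atrial tissue is argued against, since its position on atrial genes was 0.21 (0.15 to 0.36). The ventricular arrays of that age reached at most 0.03 on these genes. On ventricular genes its position of 0.29 (0.21 to 0.52) overlapped that of E14.5 ventricular array 2, 0.24 (0.07 to 0.58). A wrong label of a ventricular sample with some atrial tissue is therefore not excluded. Ventricular tissue in the atrial samples may account for arrays 1 and 2 of E14.5, since the positions on atrial and on ventricular genes differed by -0.08 (-0.32 to 0.07) and 0.03 (-0.01 to 0.14). Cushion or valve tissue in array 1 stays open: the list was at percentile 100 of 10000 random lists, which only repeats what had been seen there, and at percentile 4.9 on array 2 (against array 3), where ventricular genes were high as well, and no biological explanation was tested.

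Heart genes at E11.5 lay near the level of isolated E12.5 hearts, although the description names the middle part of the embryo. Samples of mostly other tissue are argued against, since the median difference was -0.05 (-0.15 to 0.11) for 47 ion channel and transcription factor genes together. It was 0.11 (-0.05 to 0.24) for the ion channel list and -0.17 (-0.47 to -0.07) for the transcription factor list, the latter being lower in isolated hearts. The ranges in this paragraph also came from resampling genes and hold no spread between samples. The ventricular chamber list, at -0.46 (-0.80 to -0.25), cannot decide this, because the isolated heart was the mean of both chambers. Its list score was 0.44, 0.42 and 0.45 on the E11.5 arrays and 0.77, 0.76 and 0.83 on E12.5 ventricular arrays. On E12.5 atrial arrays that score was -1.33, -0.25 and -1.38. Cushion and outflow tissue left out when the chambers were isolated could account for the lower cushion genes, with a median of -0.65 (-1.09 to -0.37). That cannot be told apart from age, because each stage had 1 kind of dissection. A change with age stays open and untested.

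Single arrays held lung or liver genes at high levels, such as Sftpc at 1745, 5694 and 10949 on atrial array 3 of E13.5, E16.5 and E18.5, and Alb at 6352 on E12.5 atrial array 2 and 4237 on E16.5 ventricular array 2. Liver tissue carried into E12.5 atrial replicate 2 and E16.5 ventricular replicate 2 may account for these, since 90% of 10 liver genes were at least 2-fold above both other arrays of the group in each case, and the share was also 70% on E18.5 ventricular array 3 (Alb at 1067) and 50% on E13.5 ventricular array 3, which were kept in the fit without liver-gene arrays. For lung tissue the share on the E18.5 array was 50% of 10 foregut and lung genes, between the bounds set in advance, so lung tissue cannot be told apart from other sources there. On the E13.5 and E16.5 arrays the share was 70% and 80%. No biological explanation was tested for these arrays.

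The following genes differed between atrium and ventricle in the change from E12.5 to E18.5 by the direct test, given as the log2 change in atrium minus that in ventricle. The difference was positive for Lyz1 (3.52), Has1 (3.43), Scgb3a2 (3.33), Dhx38 (2.86), Thbs3 (2.72), Hdc (2.70), Tmem100 (2.67), Kcnc2 (2.66), Tgfbi (2.65), Sall1 (2.63), Bmp10 (2.32) and Tbx5 (1.36). It was negative for Cpa1 (-3.33), Rhd (-2.87), Kcna5 (-2.80), Cacna1g (-2.66), Rtl3 (-2.59), Steap4 (-2.39), Reln (-2.15), Ankrd23 (-2.06), Bad (-2.02), Tuba4a (-2.00) and Myh6 (-0.73). Without E12.5 atrial array 1 the calls of Bmp10 (adjusted p = 0.058), Dhx38 (2.18, adjusted p = 0.072) and Kcnc2 (2.19, adjusted p = 0.072) were lost, and Thbs3 had adjusted p = 0.097 with the compared arrays alone. Without the arrays with high lung genes the adjusted p was 0.075 for Has1, 0.14 for Scgb3a2, 0.079 for Tbx5, 0.12 for Rhd, 0.15 for Steap4, 0.12 for Reln, 0.056 for Ankrd23, 0.13 for Bad and 0.11 for Myh6, and these genes lost their calls in other settings too.

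Other splits of the same arrays were fitted for each count. For the mean over 5 ages, 1 of 100 splits gave as many probe sets, the real one, with 11570 for the real split and 4860 for the highest other. This argues against chance if the 3 arrays of a group are independent samples, which the labels do not say. For the difference between chambers, 10 of 100 splits gave as many, with 1030 for the real split and 5725 for the highest other. The 9 others with as many all kept the ages whole in 1 chamber and mixed them in the other, so that they held an age change and say nothing on chance, which stays open here. The 84 splits that mixed the ages in both chambers gave at most 5. For the isolated heart at E12.5 against E11.5, 8 of 84 splits gave as many, with 255 and 2392. The 7 others with as many all had more arrays of 1 chamber than of the other in the place of E11.5, the highest, 2392 and 1352, with all 3 atrial or all 3 ventricular arrays, so that they held a chamber difference and say nothing on chance, which stays open here too. The 27 splits with 1 array of each kind gave at most 39. The other 12 comparisons had 10 splits each, too few for a share under 0.05. The real value and the highest other were 2637 and 682 for atrium against ventricle at E12.5, 3310 and 0 at E13.5, 1684 and 368 at E14.5, 4600 and 253 at E16.5, and 5314 and 4 at E18.5. In the ventricle they were 7835 and 1 for E18.5 against E12.5, 17 and 119 for E14.5 against E12.5, where 3 splits gave as many, and 3791 and 12 for E18.5 against E14.5. In the atrium they were 6610 and 3, 539 and 1388, where 2 splits gave as many, and 1956 and 26. For E11.5 against E10.5 they were 315 and 1.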

How the results depend on the processing

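The mean without E14.5 and the fits without arrays with high lung or liver genes were chosen after the result was seen, and the other settings given here were fixed in advance. Among 571 values of named genes, 484 were called, and 132 of these lost the call in at least 1 setting, 112 of them when 1 array was left out. Over all 15 comparisons 143 list results were called, and 21 of these also with an estimated correlation. In the 6 comparisons that were not of a single age or a shorter interval, 53 were called, 6 of them also with an estimated correlation, and 21 lost the call in a setting other than that and the leaving out of 1 array. Of the counts, 41 moved by over 1.5 times and 124 did not in the settings other than the leaving out of 1 array. The cause was not tested, except that fewer arrays or probe sets enter the settings that leave some out. The labels do not say whether replicate numbers pair the samples. Of 15 pairs of an atrial and a ventricular array that share a number, 1 had a residual correlation above 0.1, within -0.34 to 0.16. No pairing was seen in these values, which cannot exclude that the samples share embryos. With the replicate number as a block the count for atrium against ventricle, mean of 5 ages was 10963, and that for ventricle, E14.5 against E12.5 was 0. The array weights were 0.28, 6.92 and 0.51 for E12.5 atrial arrays 1, 2 and 3. With these weights the E12.5 atrial mean rested mostly on array 2, which held high liver genes. Array weights gave 6994 for atrium against ventricle at E12.5, 5044 for atrium against ventricle at E13.5, 670 for atrium against ventricle at E14.5, 8474 for atrium against ventricle at E18.5, 1924 for atrium, E14.5 against E12.5, 12642 for atrium, E18.5 against E12.5, 4733 for difference between chambers in the change from E12.5 to E18.5, 2907 for isolated heart at E12.5 against middle part of the embryo at E11.5, 2417 for middle part of the embryo, E11.5 against E10.5 and 366 for ventricle, E14.5 against E12.5. A fit of the compared arrays alone gave 279 at E12.5 and 29 at E14.5 between chambers, 0 and 4051 in atrium from E12.5 to E14.5 and to E18.5, 407 for the difference between chambers, 114 for the isolated heart, 2218 for E11.5 against E10.5 and 0 for the ventricle from E12.5 to E14.5. It gave 807 for atrium, E18.5 against E14.5 and 2062 for ventricle, E18.5 against E14.5. Median centring gave 1730 between chambers at E12.5, 236 in atrium from E12.5 to E14.5 and 1187 from E14.5 to E18.5, 425 for the difference between chambers, 165 for the isolated heart, 123 for E11.5 against E10.5 and 10 for the ventricle from E12.5 to E14.5. Without arrays with high lung genes the counts were 2198 between chambers at E13.5, 3454 at E18.5, 1076 in atrium from E14.5 to E18.5 and 490 for the difference between chambers, and without those with high liver genes 226 in atrium from E12.5 to E14.5. The strict filter gave 7319 for the mean of 5 ages and 36 for the ventricle from E12.5 to E14.5. That last count was 0 without a filter, without the trend and with a pseudocount of 68, and 73 under quantile normalization, while the atrium from E12.5 to E14.5 had 317 without a filter and 337 without the trend. Leaving out 1 array gave between 1228 and 3419 between chambers at E12.5, 1986 and 2487 at E13.5, 545 and 1954 at E14.5, 3065 and 3844 at E16.5, and 3507 and 4721 at E18.5. It gave between 0 and 2290 in atrium from E12.5 to E14.5, 3817 and 7409 from E12.5 to E18.5, 1069 and 2235 from E14.5 to E18.5, 0 and 851 in ventricle from E12.5 to E14.5, 2037 and 3757 from E14.5 to E18.5, 452 and 2014 for the difference between chambers, 40 and 340 for the isolated heart, and 61 and 214 for E11.5 against E10.5. Directions turned only for genes that were not called. In the atrium from E12.5 to E18.5, array weights gave -2.03 for Irx4 and -0.83 for Myh7, the mean of probe sets 0.13 for Myh6 and 0.36 for Myl4, the fit without arrays with high lung genes 0.13 for Myl2, and quantile normalization 0.11 for Myh6, 0.02 for Myl4, 0.02 for Myl7, 0.07 for Nppa and 0.02 for Tnni1. In the ventricle, array weights gave 0.07 for Myh7, 0.11 for Myl2 and 0.10 for Tnni1, median centring 0.02 for Irx4, 0.01 for Myh7, 0.06 for Myl2 and 0.05 for Tnni1, and quantile normalization -0.02 for Nkx2-5 and 0.01 for Tnni1. For the difference between chambers, array weights gave -2.01 for Irx4 and -0.90 for Myh7, the fit without arrays with high lung genes 0.14 for Myl2, and quantile normalization 0.01 for Tnni1. For E11.5 against E10.5, quantile normalization gave 0.01 for Myl2 and 0.06 for Myl4, and the mean of probe sets 0.00 for Myl4. For the isolated heart, the mean of probe sets gave -0.12 and quantile normalization -0.02 for Myl4, and array weights 0.01 for Myl7. With 1 array left out, values ranged from -0.79 to 1.49 for Irx4, -0.14 to 1.20 for Myh7 and -1.83 to 0.13 for Myl2 in the atrium, and from -0.74 to 1.54, -0.08 to 1.26 and -1.82 to 0.14 for the difference between chambers. In the ventricle they ranged from -0.08 to 0.01 for Irx4, -0.16 to 0.10 for Myh7, -0.09 to 0.12 for Myl2, -0.05 to 0.11 for Nkx2-5, -1.47 to 1.42 for Sln and -0.12 to 0.13 for Tnni1. Myl7 ranged from -0.11 to 0.10 for the isolated heart, and Bmp10 from -0.55 to 0.08 between chambers at E12.5. Between 46.1% and 55.6% of probe sets of an array lay above the filter intensity of 171.8, and log2 differences of genes below it depend on the pseudocount of 17, while Nppa, with values up to 19967, lay near the top of the measured range.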

Other observations

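Some gene groups had changes at single ages that the account above left out, and their lists were fixed in advance, while leaving out single arrays for these lists was chosen only after the result was seen. At E12.5, 6 of 11 conduction system genes were higher in atria and 1 lower (adjusted p = 0.019 for the list with an estimated correlation), and at E14.5 there were 5 higher (adjusted p = 0.032 with an estimated correlation). Without E12.5 atrial array 3 the first had adjusted p = 0.057, and without E14.5 ventricular array 3 the second adjusted p = 0.067, both with an estimated correlation, while 3 were higher without E14.5 ventricular array 1. Epicardial genes were higher in atria for 7 of 12 members at E12.5, 8 at E13.5, 6 at E14.5, 11 at E16.5 and 9 at E18.5, with adjusted p = 0.055, adjusted p = 0.031, adjusted p = 0.041, adjusted p = 0.015 and adjusted p = 0.13 with an estimated correlation. That of E13.5 was adjusted p = 0.065 without ventricular array 1 and adjusted p = 0.069 without atrial array 1, and that of E14.5 adjusted p = 0.056 and adjusted p = 0.091 without ventricular array 1 or 3, while 3 genes were called without E14.5 atrial array 3. Of 19 glycolysis genes, 8 were lower in atria at E12.5, 11 at E13.5 and 15 at E18.5, the last with adjusted p = 3.2e-09 and adjusted p = 0.14 with an estimated correlation, and 7 at E13.5 without atrial array 1. At E18.5, 6 of 13 macrophage and leukocyte genes were higher in atria, with 8 when adjusted over the list alone (adjusted p = 0.00047; adjusted p = 0.28 with an estimated correlation). Of 10 liver genes, 4 were higher in atria at E12.5, with 7 when adjusted over the list alone (adjusted p = 0.00033; adjusted p = 0.33 with an estimated correlation), and E12.5 atrial array 2 held Alb at 6352 and Afp at 8704. Without that array or ventricular array 2 none was called, and 1 without ventricular array 3.

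In the atrium from E14.5 to E18.5, 4 of 14 atrial chamber genes rose, with 5 when adjusted over the list alone (adjusted p = 0.0014; adjusted p = 0.44 with an estimated correlation), and 2 of 14 ventricular chamber genes fell, with 5 when adjusted over the list alone (adjusted p = 0.0014; adjusted p = 0.44 with an estimated correlation). Cushion and valve genes fell for 4 of 20 members over the same interval, with 6 when adjusted over the list alone (adjusted p = 0.0048; adjusted p = 0.44 with an estimated correlation). These changes depended on single arrays of E14.5. List scores, as the mean log2 value minus the mean over the 36 arrays, were -0.19, 0.84 and 0.84 for atrial chamber genes on atrial arrays 1, 2 and 3 of that age, 0.21, 0.34 and -0.97 for ventricular ones, and 0.84, 0.08 and 0.24 for cushion genes. Without E14.5 atrial array 1, adjusted p = 0.28 was found for the atrial list and adjusted p = 0.19 for the cushion list, with 2 cushion genes called, and without array 2 adjusted p = 0.095 for the ventricular list. The ventricular genes called were 1, 1 and 5 without E14.5 atrial array 1, 2 or 3 and 5, 1 and 0 without E18.5 atrial array 1, 2 or 3.

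Some values on single arrays stood apart from the others of their group. On E12.5 atrial array 1, Mki67 was at 9959, against 3991 and 3578 on the other atrial arrays of that age, and Rhd was at 6874, Kel at 7879 and Nfe2 at 3957. On ventricular array 1, Sln was at 567 at E13.5 and 1789 at E18.5. Xist was at 304 on E11.5 array 3 and 414 on E14.5 ventricular array 1.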
